A study of Homo sapiens with 6 samples.

How the data were processed

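Total RNA from 6 cultures of MCF10ATk1 cells, 3 treated with DMSO and 3 with Y27632 and ML7 for 6 h, was amplified and biotin-labelled with an Illumina TotalPrep kit and hybridized to Illumina bead arrays, per the labels' protocols. The groups and the replicate numbers were taken from the labels, which describe 3 independent biological replicates per condition run in parallel. The deposited table of unnormalized values holds, for each of 47323 probes and each array, a signal intensity on a linear scale and a detection p-value, which is given to 2 decimals. It also held 6 empty lines, which were left out. A table of processed values of the same arrays was deposited too; its values are intensities on a linear scale, per the deposited values themselves, and they kept the rank order of the unnormalized signals on each array (Spearman correlation 1). Each array of that table has a median of 66.4 and the same sorted values, so the arrays were brought to a shared distribution; whether the background was corrected is not given in the sources used here. The package lumi is named in the submitters' processing notes, without a version or a role.

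Probes were given genes through the platform annotation supplied for the arrays. It lists 1 gene for 30113 probes, several genes for 8 and no entry for 17202; probes without an entry are unnamed here. Symbols were updated through gene IDs with a RefSeq table of assembly GRCh38.p14, in which 30074 probes matched, and no coordinates are given because the sources used here name no genome build.

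The unnormalized intensities were background-corrected and quantile-normalized with neqc in limma 3.58.1 under R 4.3.3, which estimates the background from the detection p-values and adds an offset of 16, and were then on a log2 scale. A probe was kept if its detection p was under 0.01, which means 0.00 at the 2 decimals given, on at least 3 of the 6 arrays. This left 14710 probes, of which 11849 had 1 gene, and for the 2249 genes with several kept probes the brightest probe by its mean over all arrays was used, so that 9153 genes were tested. The inhibited and control groups were compared with limma's lmFit and eBayes, without further covariates, and p-values were adjusted with the Benjamini-Hochberg method; a gene was called at an adjusted p under 0.05. The moderated test had 13.3 degrees of freedom per gene, and the median standard error of the log2 fold change was 0.11. Errors beside log2 fold changes are these standard errors, and log2 fold changes are inhibited minus control. Adjusted p-values of genes in the text are from limma, and those of gene lists from camera.

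Before the data were examined, 24 gene lists with 419 genes were fixed, for lipid synthesis, contractility and its known targets, growth, stress, inflammation and epithelial identity, and for other cell types. Of these genes 298 were measured, 93 were not detected and 28 have no listed probe and were not analysed here. Lists were tested with camera in limma at a preset correlation of 0.01, which treats genes as nearly independent, with the Benjamini-Hochberg method over the 24 lists. The same test with the correlation estimated from the residuals has only 4 residual degrees of freedom, against 9151 with the preset value, and fry was run beside it. The genes named in the text follow a rule fixed at the same time: the 10 largest increases and the 10 largest decreases among called genes whose groups do not overlap; in each list up to 4 measured members with the lowest p, and every called member of the cholesterol, fatty acid, YAP/TAZ and MRTF/SRF lists; and, where measured, ROCK1, ROCK2, MYLK, LPIN1, SREBF1, SREBF2, INSIG1, CCN1, CCN2, ANKRD1 and 1 further gene that was not analysed here. This rule took 136 tested genes. Where a list had 5 or fewer called members in a direction, those outside the rule (DDIT3, PFKM, IER3 and HSPH1) are named too, chosen after their values were seen, as were FOS and the members named from the 3 added lists. Other probes of a named gene are mentioned where they differ from the probe used by more than 0.5 on the log2 scale or in sign, which held for ACSS2, INSIG1, MSMO1, CD68 and DCN. Those of ZMAT3, which differed by less, are given too.

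The procedure was tested on simulated data for the inhibited against control comparison, with the means and spreads of the 9153 genes drawn independently and 200 genes changed by known amounts. It called 87.0% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1, and 5.08% of its calls were unchanged genes. In a second simulated set, drawn with the same means and spreads, only the genes of 1 list changed. That list of 18 genes, shifted by 0.5, was called and none of 23 unshifted lists was. The shifted list also passed camera with an estimated correlation (adjusted p = 0.0017). Simulated genes were independent and already on the normalized scale. The simulation therefore does not test lists with correlated members, the background correction or the normalization. Nor does it test lists set against other genes of which many change, as in the real data.

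Alternatives fixed before the data were examined were no background correction, median centring in place of quantile normalization, normexp with an offset of 50, the submitters' processed values, no filter on dim probes, detection on all 6 arrays, a detection p under 0.05, the mean of a gene's probes, a variance trend with robust moderation, array weights, the replicate number as a block, each array left out in turn, and an adjusted p under 0.01. The slide as a block was not run because the columns name no slides. Lists of FOXO targets, of lysosome and autophagy genes and of ribosome biogenesis genes were added after the largest changes had been seen and are reported only among the closing observations. They were tested without the 40 largest changes each way, which the test of the 24 lists kept and which held no member of these 3 lists. Their p-values were adjusted over these 3 lists and also over all 27.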

Results

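Gene expression was measured on Illumina bead arrays in MCF10ATk1 cells, also called MII, a human mammary epithelial line derived from immortalized MCF10A cells by transformation with HRAS. Sparse cultures on plastic received DMSO, the solvent control, or a mixture of 20 µM Y27632 and 20 µM ML7 for 6 h. Y27632 inhibits the ROCK kinases, and ML7 inhibits myosin light chain kinase, so that both compounds lower the activity of non-muscle myosin and with it the contractility of the cells. Each group held 3 arrays from independent biological replicates, and this number of arrays limits the precision of every value below. The comparison asks which transcripts change when contractility is inhibited. The 2 inhibitors were given only together, so their separate effects were not analysed here.

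The inhibited arrays were brighter than the control arrays before normalization. Their mean raw signals were 213, 216 and 202, against 189, 197 and 192 on the control arrays, and they detected 15063, 15086 and 14532 probes against 14255, 14653 and 14277. After normalization, arrays of one group correlated over the 9153 genes tested at r = 0.991 to 0.994 and arrays of different groups at r = 0.981 to 0.987. The first principal component held 56.9% of the variance and separated the 2 groups. At most 48 of 47323 probes had identical raw values on any pair of arrays, so no array was a copy of another.

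After inhibition of ROCK and MLCK, genes of lipid synthesis rose and targets of the actin-regulated factors MRTF and SRF fell. With an estimated correlation the cholesterol list passed (adjusted p = 0.0237), and the fatty acid list (adjusted p = 0.0678) and the MRTF/SRF list (adjusted p = 0.116) did not. HMOX1, which encodes heme oxygenase 1, had the largest increase, with a log2 fold change of 2.33 ± 0.26 (SE, n = 3 per group; 5.03-fold, adjusted p = 0.000114), from a normalized log2 signal of 4.98 ± 0.24 (SD) in the control group to 7.31 ± 0.73 in the inhibited group. Its log2 fold change was 1.10 without background correction and 1.46 with normexp and an offset of 50; under these alternatives and with the submitters' processed values, where HMOX1 lay between those values, ACSS2 had the largest increase (1.41 without background correction). ACSS2, the cytosolic acetyl-CoA synthetase, rose by 1.58 ± 0.09 (2.98-fold, adjusted p = 1.14e-06), and LPIN1, a phosphatidate phosphatase of glycerolipid synthesis, by 1.31 ± 0.10 (2.48-fold, adjusted p = 5.85e-06). TAGLN, which encodes the actin-binding protein transgelin, had the largest decrease, with a log2 fold change of -1.94 ± 0.10 (3.83-fold lower, adjusted p = 1.84e-07), from 8.99 ± 0.10 (SD) to 7.05 ± 0.03. THBS1, which encodes the adhesive glycoprotein thrombospondin 1, had a log2 fold change of -1.19 ± 0.23 (adjusted p = 0.0032), and did not pass with a variance trend and robust moderation (adjusted p = 0.0872, in a range of 0.000251 to 0.0872 over 17 alternatives).

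Among the other genes with the 10 largest increases, TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein, rose by 1.64 ± 0.11, PDK4, a pyruvate dehydrogenase kinase, by 1.47 ± 0.11, and TP53INP1, a p53-inducible gene, by 1.37 ± 0.11. IDI1, an isomerase of the mevalonate pathway, rose by 1.26 ± 0.11, the ubiquitin ligase gene FBXO32 by 1.26 ± 0.19, FNDC3A by 1.22 ± 0.12 and the autophagy gene WIPI1 by 1.21 ± 0.11. FBXO32 was detected on 2 of the 3 control arrays. Among the other genes with the 10 largest decreases, the keratin gene KRT80 had a log2 fold change of -1.55 ± 0.11, the interferon-inducible GTPase gene GBP1 of -1.28 ± 0.10, RFTN1 of -1.26 ± 0.11, the cytokine receptor gene IL7R of -1.24 ± 0.12 and FAM83A of -1.22 ± 0.16. EVA1A stood at -1.14 ± 0.13, the chemokine gene CXCL8 at -1.10 ± 0.14 and DLK2 at -1.09 ± 0.10. The changes of these 20 genes depended on the background correction: 13 of the 20 were smaller by over 1.5 times without it, 9 with normexp and an offset of 50 and 12 with the submitters' processed values, and all 20 passed under these 3 alternatives. The same held beyond these 20: of the 109 called genes that the rule names, 45 were smaller by over 1.5 times without background correction, 27 with normexp and an offset of 50 and 38 with the submitters' processed values, while 101, 105 and 103 still passed.

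**Figure D1:**
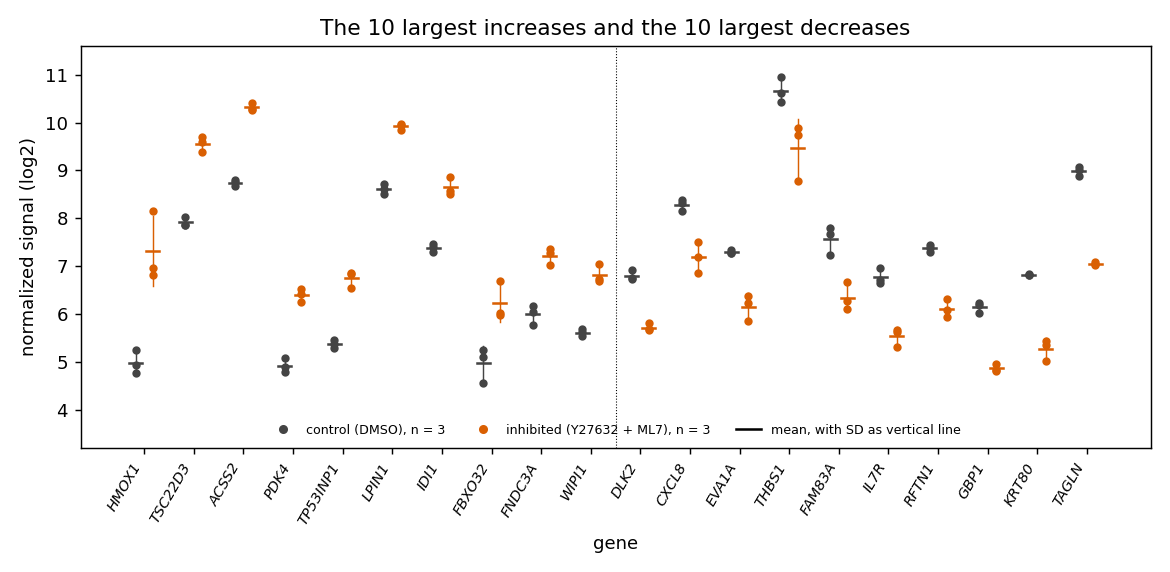
Normalized log2 signal (vertical axis) of the 10 genes with the largest increase and the 10 with the largest decrease (horizontal axis), for the 3 control and the 3 inhibited arrays, with the mean as a horizontal line and the SD as a vertical line. HMOX1 rose from 4.98 to 7.31, with 1 inhibited array at 8.15 and the others at 6.82 and 6.97, and TAGLN fell from 8.99 to 7.05.

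Of 9153 genes tested with limma, 877 were higher and 929 lower after inhibition at a Benjamini-Hochberg adjusted p under 0.05, together 19.7% of the genes. Most of these changes were small: the median size of the log2 fold change among the called genes was 0.43, and 22 genes rose and 16 fell at least 2-fold. In 3400 genes (37.1%) the groups did not overlap, where chance gives 10%. Higher genes made up 48.6% of the calls with quantile normalization and 88.0% with median centring, which moved the median log2 fold change of all genes from 0.00 to 0.16 and gave 1947 higher and 265 lower genes. None of the 1806 called genes changed sign with median centring. The count of higher genes was 478 without control replicate 1 and 571 without inhibited replicate 2, and that of lower genes 506 without control replicate 1 and 616 without control replicate 2. Without background correction, 7 genes in place of 38 reached a 2-fold change.

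Genes of cholesterol synthesis and uptake rose together. Of 18 measured members of this list, 15 were higher, none was lower, and 3 did not pass. Adjusted over the list alone, 16 were higher. Over 17 alternatives 12 to 17 members were higher and none was lower, with 12 where any control array or inhibited replicate 1 was left out. Among the smaller calls, NSDHL (0.30) passed in 7 of 17 alternatives, and HSD17B7 (0.39) and TMEM97 (0.35) each in 9 of 17. INSIG1, which encodes a sterol-regulated protein that retains SREBP in the endoplasmic reticulum, rose by 1.17 ± 0.10 on the log2 scale (adjusted p = 1.25e-05), IDI1 by 1.26 ± 0.11 (adjusted p = 2.36e-05), HMGCS1, the cytosolic HMG-CoA synthase, by 0.86 ± 0.09 (adjusted p = 8.73e-05) and the sterol desaturase gene SC5D by 0.95 ± 0.10 (adjusted p = 9.2e-05). The mean log2 fold change of the list was 0.69, with a camera adjusted p = 3.69e-14 and an adjusted p = 0.0237 with an estimated correlation. The other kept probe of INSIG1, a dimmer one, gave 0.32. MSMO1, a methylsterol oxidase gene at 0.91 ± 0.11, had another probe at 0.84 and a dimmer one at -0.09. SREBF2, which encodes the transcription factor SREBP2, was detected on 1 of 3 arrays in each group and was not tested.

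Fatty acid and glycerolipid synthesis genes also rose. Of 16 measured members, 8 were higher, none was lower, and 8 did not pass. Adjusted over the list alone, 10 were higher. Over 17 alternatives 6 to 12 members were higher and none was lower, with 6 without control replicate 1 or inhibited replicate 1. FASN (0.37) passed in 11 of 17 alternatives and ME1 (0.37) in 13 of 17. After ACSS2 and LPIN1, the long-chain acyl-CoA synthetase gene ACSL1 rose by 0.83 ± 0.13 (adjusted p = 0.00121) and SCD, the stearoyl-CoA desaturase, by 0.54 ± 0.09 (adjusted p = 0.00161). Of the other kept probes of ACSS2, one gave 1.55 and a dimmer one 0.33. SREBF1, which encodes SREBP1, was at 0.19 ± 0.10 (adjusted p = 0.186) and passed with median centring (0.38, adjusted p = 0.0233, in a range of 0.0233 to 0.361 over 17 alternatives). The list had a mean log2 fold change of 0.39 and a camera adjusted p = 3.26e-05, which became an adjusted p = 0.0678 with an estimated correlation. In the list of cholesterol efflux and LXR targets, SMPDL3A was higher (0.87 ± 0.10), the other 4 of 5 measured members did not pass, and the list as a whole did not pass (mean 0.25, camera adjusted p = 0.112); it passed without the filter on dim probes (adjusted p = 0.0326) and without inhibited replicate 1 (adjusted p = 0.0287, in a range of 0.0287 to 0.177 over 17 alternatives).

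**Figure D2:**
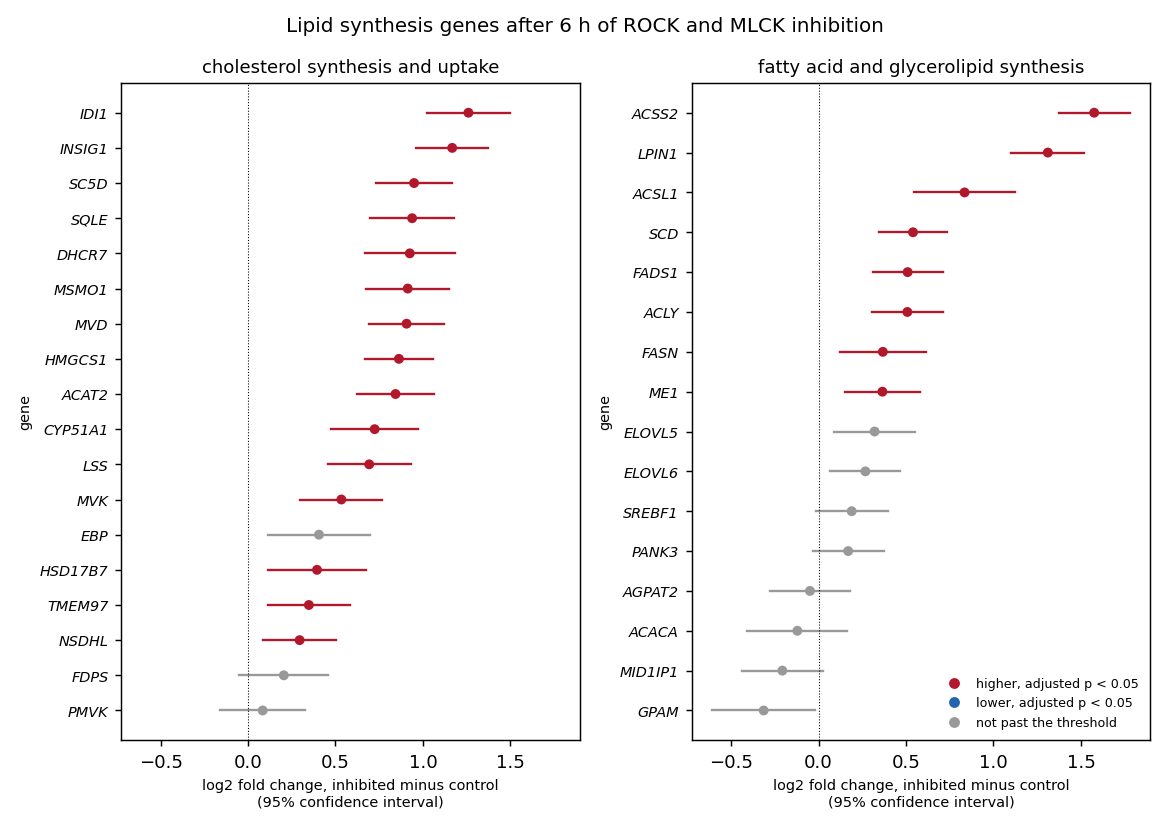
Log2 fold change with its 95% confidence interval (horizontal axis) for each measured gene (vertical axis) of the cholesterol list on the left and the fatty acid and glycerolipid list on the right, inhibited minus control, with 3 arrays per group. Red points passed an adjusted p under 0.05 as higher and grey points did not pass; 15 of 18 and 8 of 16 genes were higher and none was lower.

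Targets of the actin-regulated transcription factor pair MRTF and SRF fell. Of 19 measured members, 10 were lower, none was higher, and 9 did not pass. Adjusted over the list alone, 13 were lower. Over 17 alternatives 7 to 13 members were lower and none was higher, with 7 under median centring. TPM4 (-0.37) passed in 10 of 17 alternatives. Next to TAGLN, the calponin gene CNN2 had a log2 fold change of -0.84 ± 0.11 (adjusted p = 0.000349), the tropomyosin gene TPM1 of -0.81 ± 0.11 (adjusted p = 0.000465) and ZYX, which encodes the focal adhesion protein zyxin, of -0.76 ± 0.11 (adjusted p = 0.000641). The mean of the list was -0.44, with a camera adjusted p = 4.06e-07 and an adjusted p = 0.116 with an estimated correlation. With median centring the mean was -0.28.

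Targets of YAP and TAZ, transcriptional coactivators that respond to cell shape and tension, fell as well. Of 17 measured members, 10 were lower, none was higher, and 7 did not pass. Adjusted over the list alone, 11 were lower and 1 was higher. Over 17 alternatives 6 to 11 members were lower and 0 to 1 higher. AJUBA (-0.48) passed in 8 of 16 alternatives, FOXF2 (-0.34) in 8 of 17 and FJX1 (-0.45) in 11 of 17. IGFBP3 had a log2 fold change of -1.07 ± 0.13 (adjusted p = 0.00019), CCN1 of -0.93 ± 0.13 (adjusted p = 0.000406), CRIM1 of -0.84 ± 0.12 (adjusted p = 0.000609) and CCN2 of -0.60 ± 0.10 (adjusted p = 0.0016). ANKRD1, another target of YAP and TAZ, was not detected on any array. The list had a mean of -0.39 and a camera adjusted p = 2.79e-05, which became an adjusted p = 0.185 with an estimated correlation. With median centring, 6 members were lower and 1 was higher and the mean was -0.23; without background correction the mean was also -0.23.

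**Figure D3:**
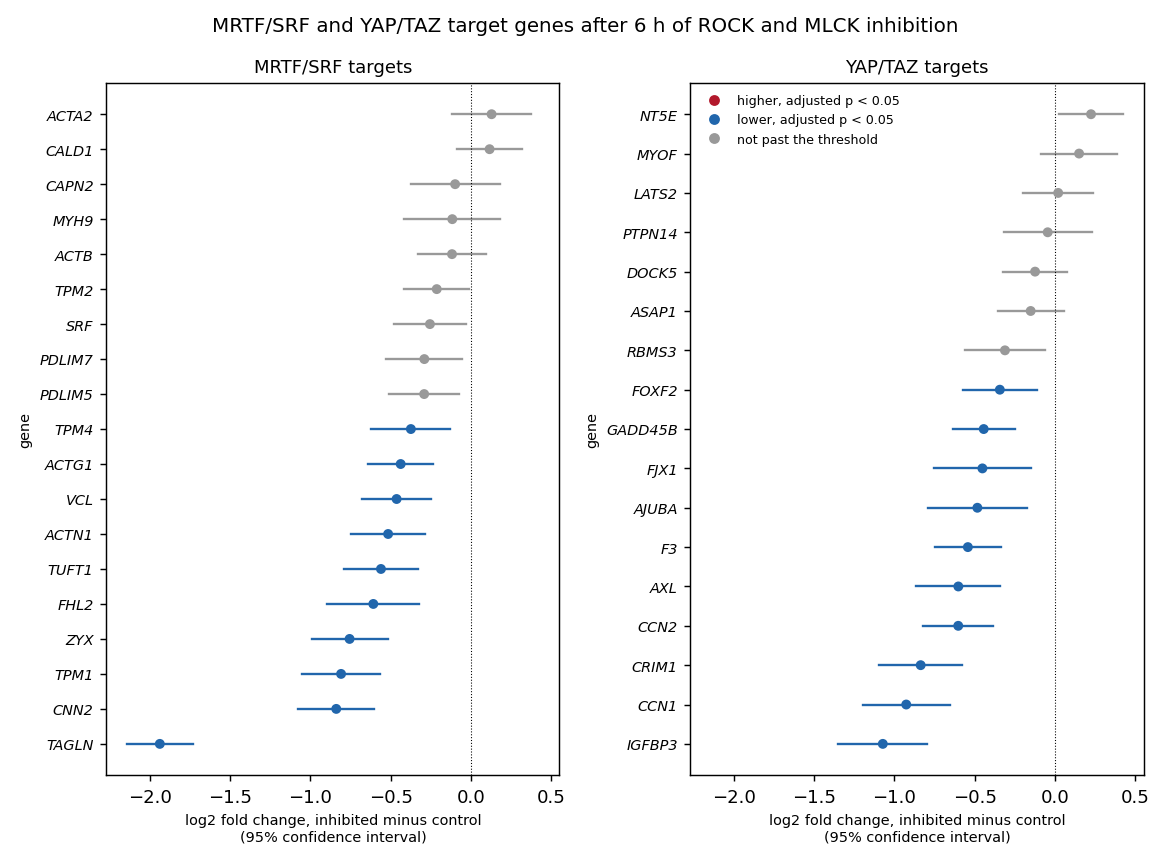
Log2 fold change with its 95% confidence interval (horizontal axis) for each measured gene (vertical axis) of the MRTF/SRF target list on the left and the YAP/TAZ target list on the right, inhibited minus control, with 3 arrays per group. Blue points passed an adjusted p under 0.05 as lower and grey points did not pass; 10 of 19 and 10 of 17 genes were lower, with TAGLN at -1.94 and IGFBP3 at -1.07.

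Genes of the G1/S transition and DNA replication fell. Of 21 measured members, 13 were lower and 8 did not pass; adjusted over the list alone, 14 were lower. The cyclin genes CCNE1 and CCND1 had log2 fold changes of -1.04 ± 0.09 (adjusted p = 2.37e-05) and -0.85 ± 0.13 (adjusted p = 0.000931), the transcription factor gene E2F2 of -0.62 ± 0.10 (adjusted p = 0.0011) and GINS2, a replication helicase subunit gene, of -0.55 ± 0.09 (adjusted p = 0.00165). The mean was -0.35, with a camera adjusted p = 1.04e-06 and an adjusted p = 0.0541 with an estimated correlation. Heat shock protein genes fell too: 5 of 11 were lower and 6 did not pass, and adjusted over the list alone 6 were lower. DNAJA1 was at -0.60 ± 0.10, HSPA1A at -0.74 ± 0.13, HSPA8 at -0.52 ± 0.11, HSPA1B at -0.47 ± 0.11 and HSPH1 at -0.34 ± 0.10, where HSPA1A and HSPA1B are nearly identical in sequence, so that their separate values are uncertain. The heat shock list had a mean of -0.33 and a camera adjusted p = 0.00025, against an adjusted p = 0.273 with an estimated correlation. With median centring, 4 G1/S genes and 2 heat shock genes were lower, and the means were -0.19 for the G1/S list and -0.17 for the heat shock list; without the filter on dim probes, 8 G1/S genes were. HSPH1 passed in 12 of 17 alternatives, with an adjusted p from 0.00238 to 0.26, and did not pass without control replicate 2 (0.0933), control replicate 3 (0.0604), inhibited replicate 1 (0.0597) or inhibited replicate 3 (0.0534).

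Targets of NRF2, the regulator of antioxidant genes, rose in 4 of 9 measured members, and 5 did not pass; adjusted over the list alone, 5 were higher. Besides HMOX1, GCLC and GCLM, which encode the subunits of glutamate-cysteine ligase, rose by 0.75 ± 0.11 (adjusted p = 0.000745) and 0.52 ± 0.10 (adjusted p = 0.0038), and PGD by 0.42 ± 0.10 (adjusted p = 0.0104). The mean of the list, which includes HMOX1 at 2.33, was 0.49 and its median 0.28. The camera adjusted p was 0.00308, and 0.185 with an estimated correlation. Without background correction the mean was 0.29. Among p53 targets, 4 of 12 were higher and 8 did not pass, and 4 were higher adjusted over the list alone: TP53INP1 at 1.37 ± 0.11, GDF15, a stress-induced cytokine gene, at 1.13 ± 0.14, ZMAT3 at 0.55 ± 0.13 and SESN1 at 0.38 ± 0.10. The p53 list had a mean of 0.31 and a median of 0.11, a camera adjusted p = 0.0168 and an adjusted p = 0.273 with an estimated correlation. Its mean was 0.17 without background correction, 0.19 with the submitters' processed values and 0.47 with median centring. Without inhibited replicate 3 its camera adjusted p was 0.0708, in a range of 0.00286 to 0.0708 over 17 alternatives. Without control replicate 1 or inhibited replicate 2, 2 of its members were higher. ZMAT3 passed in 12 of 17 alternatives, with an adjusted p from 0.00124 to 0.324, and did not pass without control replicate 1 (0.0583), inhibited replicate 1 (0.216) or inhibited replicate 2 (0.324). Its log2 fold change was 0.26 without inhibited replicate 1 and 0.20 without inhibited replicate 2. With the mean of a gene's probes ZMAT3 was at 0.29 and did not pass (adjusted p = 0.0795), and its other kept probes gave 0.25 and 0.07. SESN1 passed in 14 of 17 alternatives, with an adjusted p from 0.00329 to 0.0862, and did not pass without control replicate 1 (0.0652), control replicate 2 (0.0862) or inhibited replicate 2 (0.0595).

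**Figure D4:**
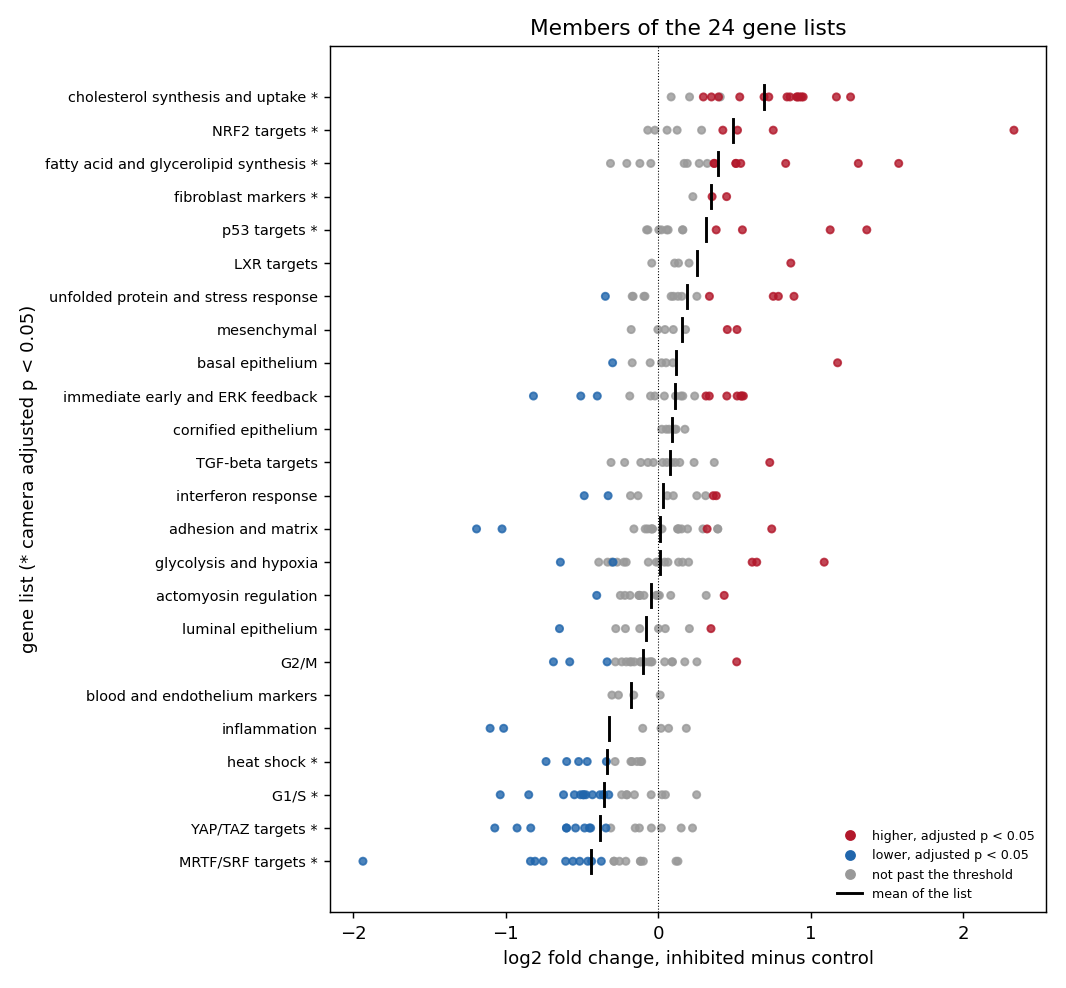
Log2 fold change, inhibited minus control (horizontal axis), of every measured member of the 24 gene lists (vertical axis), with the mean of each list as a black line and 3 arrays per group. Red and blue points passed an adjusted p under 0.05 as higher and lower, and a star marks the 9 lists with a camera adjusted p under 0.05. Of these only the cholesterol list passed with an estimated correlation. The list means run from -0.44 for the MRTF/SRF targets to 0.69 for the cholesterol list.

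In the 6 lists described in this paragraph some members changed and the list as a whole did not pass. The counts adjusted over the list alone equalled those over all genes in the remaining lists fixed before the data were examined except 3: 5 members of the unfolded protein and stress response list were higher, 6 glycolysis and hypoxia genes were lower, and 2 leukocyte and endothelial markers were lower. Among immediate early and ERK feedback genes, 7 of 18 were higher and 3 lower (camera adjusted p = 0.124), with the AP-1 subunit genes JUN at -0.82 ± 0.14 and FOSL1 at -0.51 ± 0.09 lower and FOS, another one, higher at 0.55 ± 0.12. IER3 was at -0.40 ± 0.10, and the phosphatase genes DUSP6 and DUSP1 were higher at 0.54 ± 0.09 and 0.52 ± 0.10. Without inhibited replicate 1, 4 members of this list were higher, and with median centring 1 was lower. FOSL1 did not pass with median centring (adjusted p = 0.0556, in a range of 0.00128 to 0.0556 over 17 alternatives). Of 19 adhesion and matrix genes, PLAU, the urokinase gene, was lower at -1.02 ± 0.09 together with THBS1, and the integrin genes ITGA2 and ITGAV were higher at 0.74 ± 0.12 and 0.32 ± 0.09 (camera adjusted p = 0.546); over 17 alternatives 1 to 6 members were higher, the 6 with median centring. Among 14 genes of the unfolded protein and integrated stress response, TRIB3 (0.89 ± 0.10), DNAJB9 (0.79 ± 0.11), PPP1R15A (0.75 ± 0.13) and DDIT3 (0.33 ± 0.10) were higher and SDF2L1 (-0.35 ± 0.09) was lower (camera adjusted p = 0.112). That list passed without the filter on dim probes (adjusted p = 0.0349, in a range of 0.0349 to 0.171 over 17 alternatives). Of 19 glycolysis and hypoxia genes, SLC2A3 (1.09 ± 0.12), NDRG1 (0.64 ± 0.10) and PFKFB4 (0.61 ± 0.10) were higher and PFKFB3 (-0.64 ± 0.11) and PFKM (-0.30 ± 0.10) lower; the mean of that list was 0.01, its median -0.01 and the direction of its test downward (camera adjusted p = 0.826). Over 17 alternatives 1 to 6 of its members were lower, with 1 lower where any of the control arrays or inhibited replicate 1 was left out and 4 without inhibited replicate 3. Of 21 genes of G2/M and mitosis, CDC20 (-0.58 ± 0.09), PLK1 (-0.69 ± 0.13) and BIRC5 (-0.34 ± 0.10) were lower and KIF11 (0.51 ± 0.12) was higher (camera adjusted p = 0.179), and the mean of -0.10 became 0.06 with median centring. Of 6 measured NF-kappaB targets and cytokines, CXCL8 and CXCL1 (-1.01 ± 0.16) were lower (camera adjusted p = 0.192).

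The list of kinases, myosins and other regulators of contractility did not pass (mean -0.05, and 0.12 with median centring; camera adjusted p = 0.45), and 13 of its 15 measured members did not pass. ROCK1, one of the inhibited kinases, was at 0.43 ± 0.12 (adjusted p = 0.0261), the myosin phosphatase subunit gene PPP1R12B at -0.40 ± 0.11 (adjusted p = 0.0198) and ROCK2 at 0.01 (-0.07 to 0.18 over 17 alternatives). MYLK, which encodes myosin light chain kinase, was not detected on any array. Of 13 TGF-beta and SMAD targets, BHLHE40 was higher at 0.73 ± 0.10 (camera adjusted p = 0.45), and 1 to 3 were higher over 17 alternatives. Of 10 interferon-stimulated genes, OAS1 (-0.49 ± 0.10) and IFIT3 (-0.33 ± 0.10) were lower and IFI44 (0.38 ± 0.12) and IRF9 (0.36 ± 0.12) higher (camera adjusted p = 0.826), and 0 to 4 were higher over 17 alternatives. IFI44 was detected on 2 of the 3 control arrays and IFIT3 on 2 of the 3 inhibited arrays.

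Among the lists of cell identity, that of fibroblast markers passed and the others did not. Of 7 basal mammary markers, the desmoglein gene DSG3 was higher at 1.18 ± 0.18 and KRT14 lower at -0.30 ± 0.10 (camera adjusted p = 0.826), and of 8 luminal markers KRT7 was lower at -0.65 ± 0.13 and CDH1, the E-cadherin gene, higher at 0.34 ± 0.10 (camera adjusted p = 0.56). None of 6 measured genes of squamous differentiation passed (camera adjusted p = 0.45). Of 7 mesenchymal genes, TWIST1 (0.45 ± 0.11) and ZEB2 (0.52 ± 0.15) were higher (camera adjusted p = 0.233). Of 11 fibroblast markers 3 were measured, and COL6A3 (0.45 ± 0.11) and POSTN (0.35 ± 0.09) were higher, with a mean of 0.34, a camera adjusted p = 0.0367 and an adjusted p = 0.273 with an estimated correlation. Its mean was 0.22 without background correction, 0.52 with median centring and 0.10 without the filter on dim probes. DCN, the other measured marker, was at 0.23 and did not pass, and its other kept probes gave -0.16 and 0.11. The other kept probe of COL6A3 gave 0.22 and that of POSTN 0.43. With the mean of a gene's probes the list had a mean of 0.26 and did not pass (camera adjusted p = 0.104). The fibroblast list passed in 11 of 17 alternatives, in a range of 0.0212 to 0.161. Among fits without 1 array it was lost without control replicate 2 (0.0667), control replicate 3 (0.0555) and inhibited replicate 3 (0.0804). None of 4 measured leukocyte and endothelial markers passed (mean -0.18, camera adjusted p = 0.192). CD68, 1 of these, was at -0.16, and its other kept probe gave 0.07.

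Many of the values given with the lists were smaller by over 1.5 times without background correction. Without it, CXCL1 was at -0.39, IGFBP3 at -0.59, CRIM1 at -0.43, CCNE1 at -0.55, E2F2 at -0.40, PLK1 at -0.39, FOSL1 at -0.25 and OAS1 at -0.18. Among higher genes, GDF15 was then at 0.49, DSG3 at 0.58, SLC2A3 at 0.64, SMPDL3A at 0.42, GCLC at 0.42, DNAJB9 at 0.39, COL6A3 at 0.22, POSTN at 0.22, SESN1 at 0.19 and FOS at 0.18. These 18 genes passed without background correction. ROCK1 (0.18), PPP1R12B (-0.15), ZEB2 (0.15), IFI44 (0.11), IRF9 (0.14), IFIT3 (-0.08), DDIT3 (0.10), AJUBA (-0.14) and FOXF2 (-0.15) did not.

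Several of the smaller calls named above did not pass when 1 array was left out; the adjusted p without that array follows it in parentheses. DDIT3 passed in 7 of 17 alternatives, with an adjusted p from 0.00845 to 0.169, and did not pass without control replicate 2 (0.0969), control replicate 3 (0.102), inhibited replicate 1 (0.0572), inhibited replicate 2 (0.0733) or inhibited replicate 3 (0.0625). PFKM passed in 9 of 17 alternatives, with an adjusted p from 0.0121 to 0.394, and did not pass without control replicate 1 (0.129), control replicate 2 (0.0673), control replicate 3 (0.116), inhibited replicate 1 (0.093) or inhibited replicate 2 (0.114). IER3 passed in 15 of 17 alternatives, with an adjusted p from 0.00131 to 0.111, and did not pass without control replicate 1 (0.0616). ROCK1 passed in 11 of 17 alternatives, with an adjusted p from 0.00683 to 0.103, and did not pass without control replicate 1 (0.103), control replicate 2 (0.084), inhibited replicate 1 (0.0897) or inhibited replicate 2 (0.0903). PPP1R12B passed in 13 of 17 alternatives, with an adjusted p from 0.0107 to 0.15, and did not pass without control replicate 1 (0.0882) or inhibited replicate 1 (0.0772). ITGAV passed in 12 of 17 alternatives, with an adjusted p from 0.00487 to 0.112, and did not pass without control replicate 1 (0.112), control replicate 2 (0.0614), control replicate 3 (0.0657) or inhibited replicate 1 (0.0985). SDF2L1 passed in 14 of 17 alternatives, with an adjusted p from 0.000877 to 0.17, and did not pass without control replicate 1 (0.0605) or control replicate 3 (0.0504). BIRC5 passed in 10 of 17 alternatives, with an adjusted p from 0.00555 to 0.22, and did not pass without control replicate 1 (0.142), control replicate 2 (0.0634), inhibited replicate 1 (0.0705) or inhibited replicate 2 (0.0736). IFIT3 passed in 6 of 16 alternatives, with an adjusted p from 0.0288 to 0.236, and did not pass without control replicate 1 (0.0959), control replicate 3 (0.0992), inhibited replicate 2 (0.0954) or inhibited replicate 3 (0.0769). IFI44 passed in 7 of 16 alternatives, with an adjusted p from 0.0119 to 0.148, and did not pass without control replicate 1 (0.125), control replicate 3 (0.117), inhibited replicate 2 (0.107) or inhibited replicate 3 (0.0792). IRF9 passed in 5 of 17 alternatives, with an adjusted p from 0.00675 to 0.143, and did not pass without control replicate 2 (0.142), control replicate 3 (0.131), inhibited replicate 2 (0.143) or inhibited replicate 3 (0.137). KRT14 passed in 8 of 17 alternatives, with an adjusted p from 0.0179 to 0.414, and did not pass without control replicate 1 (0.125), control replicate 2 (0.0862), control replicate 3 (0.116), inhibited replicate 1 (0.0873) or inhibited replicate 2 (0.134). CDH1 passed in 14 of 17 alternatives, with an adjusted p from 0.00533 to 0.0871, and did not pass without control replicate 1 (0.0871), control replicate 2 (0.0748) or inhibited replicate 2 (0.0672). TWIST1 passed in 16 of 17 alternatives, with an adjusted p from 0.00214 to 0.063, and did not pass without control replicate 1 (0.063). ZEB2 passed in 10 of 16 alternatives, with an adjusted p from 0.00579 to 0.114, and did not pass without control replicate 2 (0.0786), inhibited replicate 1 (0.0778) or inhibited replicate 2 (0.0759). POSTN passed in 14 of 17 alternatives, with an adjusted p from 0.00244 to 0.064, and did not pass without control replicate 1 (0.0528), control replicate 2 (0.064) or inhibited replicate 3 (0.0505). Without control replicate 2 the log2 fold change of ZEB2 was 0.31.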

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

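A signal was present in probes that the comparison of genes does not use. Of 2861 kept probes with no listed gene, 368 differed between the inhibited and control arrays at an adjusted p under 0.05 in limma, with 168 higher and 200 lower. This was 12.9% of these probes, against 17.0% of the kept probes with a gene. Of the 200 lower probes, 2 fell at least 2-fold. Which transcripts these probes measure was not analysed here, and no explanation was tested.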

How the results depend on the processing

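The direction of every called list and of every called named gene was kept under all alternatives run, while 5 named genes and 6 lists that were not called changed sign under an alternative; among all 1806 called genes, 4 had the other sign with the mean of a gene's probes. Of 109 called named genes, 78 passed in every alternative. The cholesterol, fatty acid, YAP/TAZ, MRTF/SRF, G1/S, heat shock and NRF2 lists passed camera in 17 of 17 alternatives at the preset correlation. The count of shifted lists, 9, became 1 with an estimated correlation. That test has fewer degrees of freedom by construction, and it also replaces the preset correlation of 0.01. The estimate was 0.242 for heat shock, 0.202 for fibroblast, 0.125 for YAP/TAZ, 0.084 for MRTF/SRF, 0.067 for p53 and 0.056 for NRF2. It was lower than the preset value for G1/S (0.00044) and fatty acid genes (-0.029), which did not pass either. The unadjusted camera p-value nevertheless rose from 1.3e-07 to 0.00451 for G1/S and from 6.79e-06 to 0.00847 for fatty acid genes. A lower correlation by itself would not raise it, which argues against the correlation as the cause of that rise in these 2 lists. For the other lists both changes were made together, so their effects on the count were not separated. With fry, which tests each list by itself and not against other genes, the count was 18. Median centring gave 1947 higher, 265 lower and 59 genes changed at least 2-fold, against 877, 929 and 38. Genes changed at least 2-fold numbered 7 without background correction, 8 with normexp and an offset of 50 and 8 with the submitters' processed values; the cause was not tested. At an adjusted p under 0.01, a stricter threshold by construction, the count of genes higher after inhibition was 338 and that of genes lower after inhibition 364. Leaving out 1 array, and so testing fewer samples, gave 478 to 769 higher genes, 506 to 780 lower genes, 30 to 50 genes changed at least 2-fold and 7 to 10 shifted lists. Of the 1806 called genes, 1468 passed without background correction, 1142 with median centring, 1536 with the submitters' values and 954 without control replicate 1. With the replicate number as a block, 745 genes were higher and 761 lower, 38 changed at least 2-fold and 9 lists shifted. The values gave no sign that the numbers pair the samples. Deviations of same-numbered arrays correlated at -0.013, -0.0748 and -0.15, and no array correlated best with its own number. Deviations centred within groups of 3 are tied to each other, so these correlations cannot decide on a pairing. The slide as a block was not run because the columns name no slides. With no filter on dim probes, 20046 genes were tested and 607 were higher and 686 lower, and 1255 of the 1806 called genes still passed. Log2 fold changes hardly moved (correlation 0.9999 with those of the main fit), but p-values were adjusted over more genes, which by itself lowers the counts. A limit set by dim signal was not separated from this.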

Other observations

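The 3 gene lists in the first 2 paragraphs were written after the largest changes had been seen, and their adjustment over all 27 lists was added after their results were known. The tests of signal brightness and of other probes further on were chosen after the lists they concern had been seen to shift, and the condition that at least 1 in 2 called members must have another probe was added after the values of those probes were known.

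Known targets of FOXO transcription factors, PDK4 and FBXO32, were among the 10 largest increases. To ask whether the group as a whole rose, a list of FOXO targets was tested without the 40 largest increases and the 40 largest decreases, with no gene shared with the lists fixed earlier. No member of this list, or of the lists in the next paragraph, was among those largest changes. Leaving them out therefore removed no member and is no guard against writing the list after the data were seen. Of 23 measured members, 15 were higher and none was lower (16 and 1 adjusted over the list alone). Among the higher ones were FOXO1 itself (0.85 ± 0.09, adjusted p = 0.000114), GABARAPL1 (0.86 ± 0.10), FOXO3 (0.71 ± 0.10) and the transcription factor gene KLF9 (0.69 ± 0.10). The median of the list was 0.43, at percentile 100 of 10000 random lists matched on mean signal, with a camera adjusted p = 1.93e-08 over the 3 added lists. With an estimated correlation the adjusted p = 0.015 over the 3 added lists and 0.0451 over these and the 24 earlier lists together. Without background correction GABARAPL1 was at 0.37 and the mean of the list at 0.23 in place of 0.37. As a hypothesis, FOXO activity may be higher after inhibition of ROCK and MLCK; protein levels and localization were not measured.

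Genes of lysosomes and autophagy and genes of ribosome biogenesis moved in opposite directions under the same test. Of 34 measured lysosome and autophagy genes, 13 were higher and none was lower (15 and 0 adjusted over the list alone), with RRAGC, a GTPase gene of the mTORC1 pathway, at 0.86 ± 0.10, the autophagosome gene MAP1LC3B at 0.80 ± 0.10 and SQSTM1 at 0.82 ± 0.12. The median of this list was 0.16, at percentile 99.97 of the matched random lists, with a camera adjusted p = 8.36e-08 over the 3 added lists. With an estimated correlation the adjusted p = 0.0397 over the 3 added lists, and over all 27 lists it did not pass (0.139). RRAGC was at 0.55 without background correction, and the mean of the list, 0.29, was then 0.19 and with median centring 0.46. Of 34 measured nucleolar ribosome biogenesis genes, 20 were lower and none was higher (23 and 0 adjusted over the list alone), with RRP9 at -0.74 ± 0.11, LYAR at -0.67 ± 0.11, NIP7 at -0.65 ± 0.11 and PES1 at -0.64 ± 0.11. The median of that list was -0.43, at percentile 0 of the matched random lists, with a camera adjusted p = 4.03e-12 over the 3 added lists. With an estimated correlation the adjusted p = 0.0352 over the 3 added lists, and over all 27 lists it did not pass (0.106). RRP9 was at -0.24 without background correction, -0.36 with normexp and an offset of 50 and -0.30 with the submitters' processed values, and the mean of the list, -0.37, was -0.21 with median centring. That both groups respond to the inhibitors is a hypothesis found in these data. At the preset correlation the 3 lists passed camera with the same direction in 17 of 17 alternatives, adjusted over all 27 lists as well.

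The number of genes called between the groups was set against other splits of the 6 arrays. Of 10 splits into 3 and 3, 1, the real one, gave 1806 genes or more in limma, and the highest of the others gave 0. At an unadjusted p under 0.05 the others gave 135 to 451 genes and the real split 3050. So few splits cannot give a share under 0.05.

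The rise of the lipid lists was weighed against signal brightness, since the inhibited arrays were brighter. A shift that depends on brightness would move genes of like signal together. The medians of the cholesterol and of the fatty acid list both lay at percentile 100 of 10000 random lists matched on mean signal. These lists thus moved further than genes of like signal. The test used quantile-normalized values, where the arrays already share a distribution, so a brightness-dependent shift was largely removed beforehand. It therefore cannot decide on such a shift in the raw signal. A signal specific to the probe used stays open: over the other kept probes of the called members the median log2 fold change was 0.58 for cholesterol genes (6 probes of 5 of 15 members, 5 in the same direction) and 0.45 for fatty acid genes (3 probes of 2 of 8 members), too few members to decide. A response to lower contractility also stays open as untested, and an effect of either compound on other targets was not tested.

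The fall of the MRTF/SRF and YAP/TAZ targets was weighed in the same way. Both medians lay at percentile 0 of the random lists matched on mean signal, so these lists fell further than genes of like signal. Because the values were quantile-normalized, this test cannot decide on a brightness-dependent shift of the inhibited arrays. Over other probes, the median log2 fold change was -0.60 for MRTF/SRF targets (7 probes of 7 of 10 members, all 7 lower), which argues against a probe-specific signal there. For YAP/TAZ targets it was -0.59 (4 probes of 4 of 10 members, all 4 lower), where a probe-specific signal stays open because so few members have another probe. A response to lower contractility stays open as untested, since the 2 inhibitors were given only together.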
